A study of Mus musculus with 8 samples.

How the data were processed

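RNA from 8 mouse tumors was sequenced as total RNA after depletion of ribosomal RNA, per the labels. All 8 samples carry the same genotype, Cre expressed from the Hprt locus with loxP sites placed in Ewsr1 and Atf1, so that recombination joins both genes. The tumors were frozen when the animals reached morbidity and had received no drug, per the labels' protocols. The labels name 1 group and no control, and the titles number the tumors 1, 2L, 2R, 3, 4a, 4b, 5 and 6. They do not say what a number or a suffix stands for, and none of the samples is labelled as coming from a separate animal, so every p-value below measures only the spread between these libraries.

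The authors deposited 1 table of raw gene counts, whole numbers for 49671 Ensembl gene identifiers in 8 columns. Per the submitters' processing notes, cutadapt, STAR 2.7.5a, featureCounts and RSEM were used with the mouse build mm10. The notes give neither the order of these tools nor which of them made the counts, and strand handling is not stated, so overlapping and antisense genes cannot be told apart. Identifiers were matched to the GENCODE M21 annotation of the same build, which named 49326 of them (99.31%). The 345 identifiers without a name held at most 0.0469% of the counts of a library. Coordinates are 1-based on mm10.

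Library totals ran from 4817902 counts in library 3 to 19682149 in library 2L. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low counts were removed with filterByExpr for a design of 1 group, which required 0.920 CPM before TMM scaling (10 counts in a library of median size) in each of the 8 libraries and kept 11505 genes. Genes low in some tumors, such as Dct and Acta1, were therefore not tested, and their levels are described only. Library sizes were scaled with TMM factors, which ran from 0.39 in library 3 to 1.36 in library 2L. CPM values are counts scaled by the kept counts times the TMM factor. The low factor of library 3 raises its CPM values about as much as a few very abundant RNAs lower them, so its most abundant genes have very large CPM. A prior count of 2 was added for log2 CPM. A gene with 0 counts in a library may hold up to 3 counts by chance, which is 1.60 CPM in library 3 and at most 0.467 CPM in the other 7. Such limits cover counting error only.

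Gene lists were fixed before the data were examined: lineage and signaling lists (melanocytic, neural crest and Schwann, neuroendocrine, CREB/ATF targets, receptor tyrosine kinases and ligands, proliferation, hypoxia, interferon response), markers of other cell types, Hox genes, mitochondrially encoded genes, nuclear noncoding RNA, sex-linked genes and the engineered loci with related genes. A list score was the mean log2 CPM of the members that passed the filter, and 15 lists with at least 5 such members were tested. The level of a list was the median length-scaled level of its members that passed the filter, given as a percentile among the genes kept. The SD of a score over the 8 libraries was set against 10000 random lists of the same size matched on mean expression, drawn among the 200 genes nearest in level.

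Libraries with the same number (2L with 2R, and 4a with 4b) were compared with all others by the Spearman correlation of gene-centred log2 CPM, with a one-sided exact permutation test over the 210 ways to choose 2 disjoint pairs. Genes differing among the 6 numbers were tested with edgeR's quasi-likelihood F-test with a robust prior, its spread resting on 2 residual degrees of freedom, and adjusted after Benjamini and Hochberg at 0.05. List scores were tested among numbers with a one-sided exact permutation test of the spread within pairs, and called lists were to be tested for over-representation with Fisher's exact test. Relations between scores (14 fixed pairs of lists or genes) were computed over the 6 numbers with Pearson's r and Spearman's rho and two-sided exact permutation tests. Scores of the melanocytic, skeletal muscle, adipocyte and T and NK cell lists in these relations rest on 2 to 4 members. Differences within a same-number pair have 1 library on each side and no test.

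The edgeR step was tested on simulated data in which 200 genes were changed in 1 number. With dispersions from the trend (11428 genes), 0 of 50 genes changed 2-fold, 30 of 50 changed 4-fold, 39 of 50 changed 8-fold and 43 of 50 changed 16-fold were recovered, and 5 of 117 calls were false. With gene-specific dispersions (11414 genes) the recovered numbers were 0, 22, 31 and 42, and 39 of 134 calls were false. The error rate thus exceeded its setting when the spread differed strongly between genes. Both runs gave a gene the same dispersion in every library. In the data the SD of log2 ratios was 0.909 between 2L and 2R and 0.472 between 4a and 4b. The recovered shares therefore need not hold for the real libraries.

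Genes were named by a rule fixed before the data were examined: from each list the 4 tested members of highest mean CPM and the 2 of largest SD, the called genes among title numbers (none was called by edgeR), the 10 genes of highest mean CPM, all genes of the engineered loci and the sex-linked list, the receptor tyrosine kinase and melanocytic genes, and the 5 genes with the largest ratios each way within each pair, among genes that passed the filter with a mean of at least 5 CPM in the pair. Others were chosen after their values were seen: Scg2, Scg5, Chga, Chgb, Vgf, Insm1, Th, S100b, Ngfr, Fos, Sik1, Nr4a3, Acta1, Myh4, Dsp, Krt5, Krt14, Col3a1, Acta2, Adgre1, Cd14, Aif1, Flt1, Cd3e, Adipoq, S100a8, Runx2, Myc, Pvt1 and the genes beside Myc.

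Alternatives were DESeq2 size factors, the DESeq2 1.42.0 likelihood ratio test, no filter, a mean CPM of at least 5, a prior that is not robust, counts thinned to the smallest library, other correlation measures and gene subsets, a prior count of 0.5, list medians, and leaving out each library in turn. Removal of libraries 2L and 3 together, and the filter at a mean CPM of 5 for the list results, were added after the data were seen.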

Results

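The 8 tumors arose in mice in which Cre recombination joins Ewsr1, which encodes an RNA-binding protein, to Atf1, which encodes a transcription factor of the CREB family. The corresponding human fusion is characteristic of clear cell sarcoma of soft tissue. The series was deposited for comparison with an earlier dataset that is not among the files, and it holds no normal tissue, so the 8 tumors are described here and compared with each other. The libraries held 10482087 counts in tumor 1, 19682149 in 2L, 7847571 in 2R, 4817902 in 3, 18435263 in 4a, 11263352 in 4b, 9750928 in 5 and 19388408 in 6.

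A few noncoding and mitochondrial RNAs took very different shares of the libraries. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 made up 24.7% of the counts in 2R and 0.877% in 2L. In library 3, Gm26917 and Gm42418 took 27.6% of the counts, Gm23935 took 12.3%, and the protein-coding mitochondrial genes took 18.7%, against at most 8.66%, 5.65% and 6.01% in the other 7. All remaining genes held 95.3% of the counts in 2L, 94.6% in 6, 89.7% in 4a and only 25.1% in 3. Values of library 3 therefore rest on the fewest counts, with 17952 genes detected against 21350 to 24763 in the others. The small nuclear RNA Rn7sk and the RNase P RNA Rpph1 were abundant throughout, at 18099 ± 8331 and 14713 ± 8252 CPM (SD, n = 8).

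**Figure D1:**
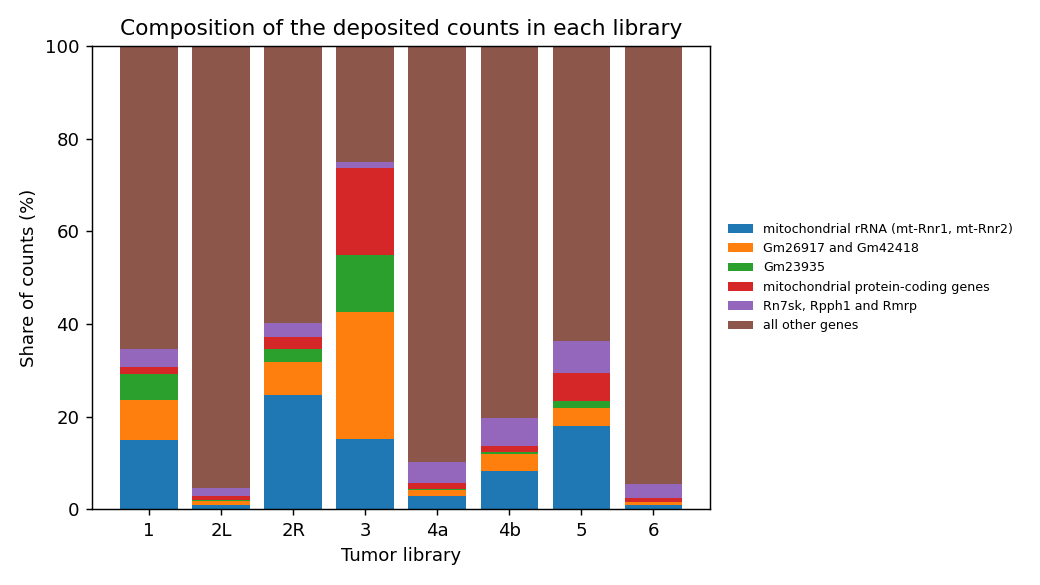
Share of the deposited counts (percent, vertical axis from 0) taken by classes of RNA in each of the 8 tumor libraries (horizontal axis), as stacked bars. All remaining genes held 25.1% of library 3 and 95.3% of library 2L.

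Ewsr1 and Atf1 were transcribed in every tumor. Ewsr1 (ENSMUSG00000009079, mm10 chromosome 11, 5069689 to 5099266) stood at 88.8 ± 25.1 CPM (SD, n = 8), from 52.2 in 2L to 129 in 5. Atf1 (ENSMUSG00000023027, chromosome 15, 100227819 to 100261244) varied less, at 27.0 ± 4.25 CPM with a range of 21.4 to 34.0. Counts per gene do not separate fusion transcripts from those of the intact alleles. Hprt, the locus that carries Cre, stood at 30.9 ± 18.5 CPM and ranged from 9.06 in 3 to 65.9 in 6. The related factors Creb1 and Crem stood at 62.9 ± 12.9 and 90.7 ± 25.6 CPM, and Fli1, a partner of the EWSR1 gene in Ewing sarcoma, at 23.07 ± 7.996 CPM.

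Sex-linked genes set tumor 5 apart. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y stood at 120, 56.9, 39.3 and 18.5 CPM in tumor 5 and at no more than 1.60 CPM in any of the other 7. Xist, the noncoding RNA of the inactive X chromosome, stood at 94.99 CPM in tumor 5 and between 343 and 1198 CPM in the others.

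Of 16 melanocytic genes, 6 reached a mean of 1 CPM. Mitf, the master regulator of melanocyte genes, was present in every tumor at 30.3 to 41.1 CPM, except in tumor 3 at 130. That higher value appears only after TMM scaling, whose low factor in library 3 (0.39) offsets the very abundant RNAs of that library. Kit, the receptor for stem cell factor, ranged from 4.44 to 62.9 CPM, and the endothelin receptor gene Ednrb from 4.99 in 4b to 365 in 2R. Dct, which encodes a pigment enzyme, reached 74.0 CPM in 3, 27.4 in 2L and 24.8 in 4b, and had no count in 6. Pmel averaged 1.04 CPM and Rab27a 5.97 CPM. The pigment genes Tyr, Tyrp1, Mlana, Slc45a2, Slc24a5 and Oca2 had no count in any of the 8 libraries, which by counting error alone allows up to 0.0257 CPM for each over all libraries together. Some mitochondrial genes that every cell uses are listed at 0 as well, so a 0 in this table does not by itself show that a gene was silent. Sox10, a neural crest regulator upstream of Mitf, did not exceed 0.235 CPM.

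Neural crest and Schwann cell genes were present in part, with 14 of 18 at a mean of at least 1 CPM. Pmp22 was the most abundant at 233 ± 88.9 CPM (SD, n = 8). Cdh19, a cadherin of Schwann cell precursors, stood at 485 CPM in tumor 6 and between 5.61 and 76.3 CPM in the others, and S100b was also highest in 6, at 114 CPM. Sox9 ranged from 13.7 to 105 CPM, Tfap2a from 1.504 to 56.46 CPM and Ncam1 from 19.1 to 60.2 CPM. Ngfr ranged from 1.81 to 40.3 CPM.

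Neuroendocrine genes were uneven, and 11 of 16 reached a mean of 1 CPM. Pcsk1, a prohormone convertase, stood at 599 CPM in tumor 1 and 39.4 CPM in 3, with a mean of 210 ± 184 (SD, n = 8). Ret, a receptor tyrosine kinase, was present in all tumors at 126 ± 52.0 CPM. Tumor 1 had the highest levels of the secretory granule genes Chgb (102 CPM), Scg3 (93.6 CPM) and Vgf (40.9 CPM) and of the synaptic vesicle gene Syp (41.2 CPM). In tumor 6 these stood at 0.650, 0.976, 0.0813 and 0.935 CPM. Other granule genes were highest elsewhere: Scg2 in 4b and 4a, at 186 and 145 CPM, Scg5 in 2L, at 49.4 CPM, and Chga in 3, at 17.0 CPM. Uchl1 was highest in 3, at 36.8 CPM. Insm1 and Th did not exceed 0.467 and 0.948 CPM.

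**Figure D2:**
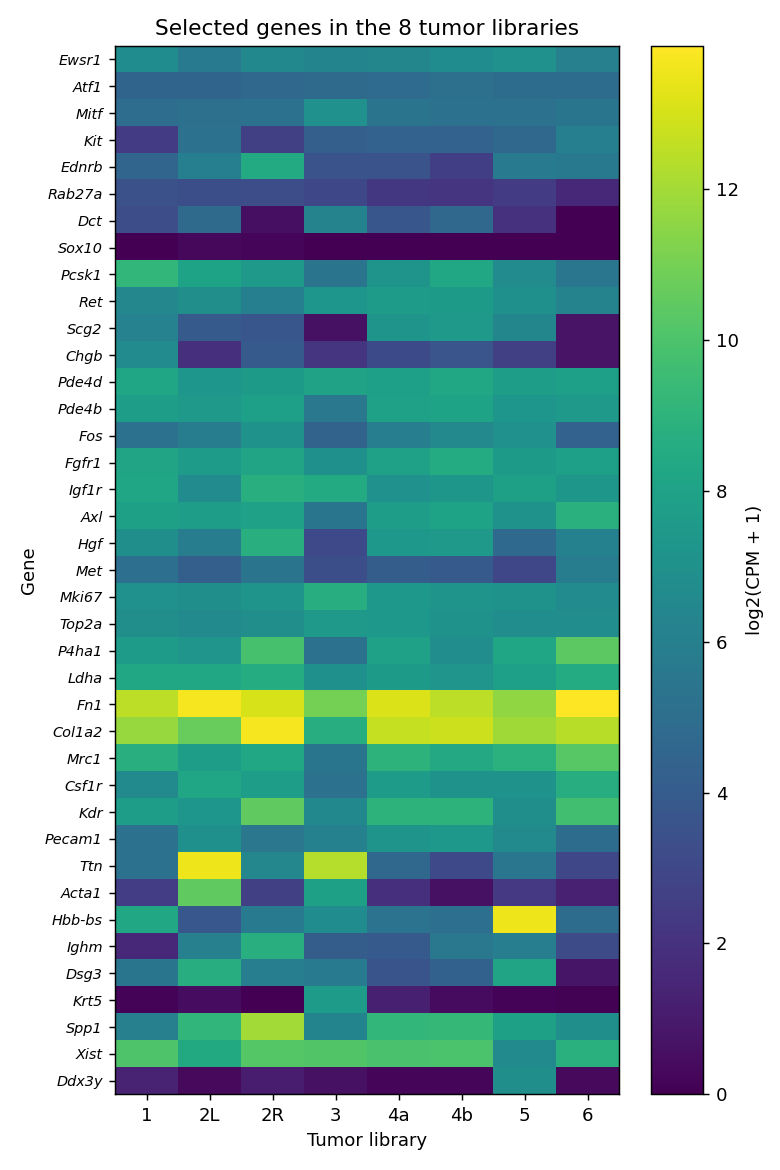
Levels of selected genes (vertical axis) in each of the 8 tumor libraries (horizontal axis), with color giving log2(CPM + 1). Ewsr1 and Atf1 are present throughout, Ttn stands out in 2L and 3, and Ddx3y stands out in 5, at 120 CPM.

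Those targets of CREB and ATF factors that passed the filter were abundant as a group, which was described and not tested. The median of these 17 members lay at the 79.6th percentile of all genes kept, and 21 of all 23 members reached a mean of 1 CPM. The phosphodiesterase genes Pde4d and Pde4b stood at 235 ± 50.1 and 191 ± 69.6 CPM (SD, n = 8), with Pde4b at 46.3 CPM in tumor 3 and at least 159 CPM elsewhere. The clock gene Per1 stood at 86.4 ± 55.2 CPM. Sik1 stood at 83.0 ± 31.6 CPM, Fos at 68.9 ± 45.4 CPM and Nr4a3 at 54.7 ± 37.6 CPM. Egr1 ranged from 3.82 to 107 CPM, and Ppargc1a, a coactivator of mitochondrial genes, from 2.19 to 70.8 CPM.

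All 18 receptor tyrosine kinase and ligand genes reached a mean of 1 CPM, and 17 reached 10. Fgfr1 (238 ± 71.8 CPM), Igf1r (232 ± 113 CPM) and Axl (227 ± 117 CPM, SD, n = 8) were the most abundant receptors of this list, which does not hold Kdr. Hgf, the ligand of Met, ranged from 7.46 CPM in 3 to 415 CPM in 2R, while Met itself stood at 24.0 ± 17.3 CPM. Nrg1, a ligand of Erbb3, was highest in 2R at 185 CPM and in 4b at 137 CPM, whereas Erbb3 was highest in 2L at 92.3 CPM and at most 13.3 CPM elsewhere. Egfr, Pdgfra and Pdgfrb averaged 59.0, 52.3 and 59.1 CPM. Kitl, Ntrk2, Erbb2, Igf2 and Alk averaged 39.1, 26.3, 21.8, 13.3 and 8.61 CPM. The list score was lowest in tumor 3, at a mean log2 CPM of 4.85, and lay between 5.56 and 6.12 in the others.

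All 20 proliferation genes passed the filter. Mki67 and Top2a stood at 169 ± 94.0 and 131 ± 30.5 CPM (SD, n = 8). Tumor 3 had the highest score (5.49, against 3.83 to 4.72), with Mki67 at 396, Foxm1 at 117 and Cdc20 at 63.4 CPM, while Rrm2 was highest in 4a at 98.1 CPM. Library 3 also had the highest share of protein-coding mitochondrial genes. Its low TMM factor (0.39) raises its CPM values about as much as its abundant RNAs lower them. The score without that factor was not computed. The hypoxia list lay at the 79.0th percentile, with the collagen hydroxylase gene P4ha1 at 1337 CPM in 6 and 908 CPM in 2R and at most 288 CPM elsewhere. Ldha, Vegfa and Ndrg1 stood at 261 ± 102, 228 ± 95.6 and 137 ± 39.8 CPM. The interferon response score was highest in 2L (5.43) and lowest in 1 (2.84), with Irf7 at 77.0 and 8.52 CPM and Ifit1 at 26.2 and 1.95 CPM. Not all members followed: Rsad2 was highest in 5 at 73.8 CPM and lowest in 2R at 4.05 CPM, and Oasl2 was highest in 4b at 50.6 CPM. Bst2 averaged 40.6 CPM.

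Genes of the extracellular matrix were among the most abundant protein-coding transcripts. Fibronectin (Fn1) stood at 7871 ± 4624 CPM, Col1a2 at 5251 ± 4062, Sparc at 2735 ± 1479, Col1a1 at 2733 ± 2443 and Col3a1 at 2233 ± 1697 CPM (SD, n = 8), and the list lay at the 96.3rd percentile. Its score was 6.66 in tumor 3 and 8.39 to 9.38 in the others. Macrophage genes lay at the 93.3rd percentile. The mannose receptor gene Mrc1 stood at 442 ± 352 CPM, Lyz2 at 283 ± 265, C1qa at 207 ± 135, Csf1r at 191 ± 116 and Cd163 at 106 ± 97.6 CPM. Tumor 6 held the highest levels, with Mrc1 at 1231 and Adgre1 at 260 CPM, and tumor 3 the lowest, with 41.01 and 21.84 CPM.

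Vessel-associated genes varied between tumors. Among endothelial genes, Kdr, the main receptor for VEGF, stood at 1430 CPM in 2R and 833 CPM in 6. Those same tumors were low in the endothelial junction genes Pecam1 (44.2 and 29.1 CPM) and Cdh5 (25.2 and 20.5 CPM), whose highest levels were 166 CPM in 4b and 126 CPM in 2L. Vwf ranged from 31.1 to 332 CPM and Flt1 from 11.9 to 74.8 CPM. The endothelial list lay at the 61.4th percentile and the smooth muscle and pericyte list at the 40.7th. Rgs5, a pericyte gene, stood at 365 ± 177 CPM (SD, n = 8), Mcam at 140 ± 86.6, Cspg4 at 41.1 ± 26.3, Acta2 at 22.7 ± 14.4 and Myh11 at 16.1 ± 12.8 CPM.

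Markers of other cell types were concentrated in particular tumors. Skeletal muscle genes were highest in 2L, where Ttn stood at 12172, Myh4 at 3343, Neb at 1597 and Acta1 at 1464 CPM, followed by library 3 with 5145, 454, 494 and 241 CPM. Library 3 held 76 genes specific to 2L, muscle genes among them, at a median of 1.19% of their counts in 2L. In the remaining 6 tumors Ttn did not exceed 84.7 CPM. Pvalb, which neurons also express, did not follow this order and was highest in 6, at 402 CPM. Hemoglobin genes were highest in 5, with Hbb-bs at 11794 and Hba-a1 at 408 CPM, against at most 327 and 21.04 CPM elsewhere. The immunoglobulin genes Ighm and Igkc were highest in 2R, at 415 and 199 CPM. The desmosome genes Dsg3 and Dsp stood at 396 and 411 CPM in 2L and at 280 and 350 CPM in 5, where the keratin gene Krt14 was at 45.6 and 55.1 CPM. Krt5, the usual partner of Krt14, stood at 193 CPM in 3 and at no more than 1.32 CPM elsewhere. Perp was present in all tumors at 540 ± 224 CPM (SD, n = 8).

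Of 15 T and NK cell markers 1 reached a mean of 10 CPM, of 12 neutrophil and mast cell markers 0, and of 11 fat cell markers 4. Cd3e did not exceed 7.45 CPM, Lck 11.1 CPM, S100a8 17.9 CPM and Adipoq 4.63 CPM. Il2rb reached 86.3 CPM in tumor 3 and at most 18.4 CPM elsewhere, and Fabp4 reached 105 CPM in tumor 5. Of the bone and cartilage genes, Spp1 stood at 3964 CPM in 2R and at 66.1 to 617 CPM elsewhere, Col2a1 ranged from 3.32 to 177 CPM, and Alpl and Runx2 averaged 63.6 and 30.2 CPM. Among 14 distal and 15 proximal Hox genes, 0 reached a mean of 10 CPM; Hoxc9 averaged 5.40 CPM.

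Libraries 4a and 4b resembled each other, whereas 2L and 2R did not. Composition also differed more between 2L and 2R. Mitochondrial ribosomal RNA took 0.877% and 24.7% of their counts, against 2.90% and 8.27% in 4a and 4b. Genes outside the abundant noncoding and mitochondrial classes held 95.3% and 59.8%, against 89.7% and 80.3%. Whether composition contributes to the contrast between the pairs was not tested. Among genes that passed the filter in all 8 libraries and averaged at least 5 CPM in the pair, which leaves out muscle genes such as Myh4 and Acta1, the largest ratios were as follows. In 2L, muscle genes (Ttn, Neb and Cmya5) and the hormone receptor genes Oxtr and Prlr exceeded 2R by 7.16, 6.70, 6.87, 6.59 and 6.57 on the log2 scale. In 2R, Mir6236, Pnoc, which encodes the precursor of nociceptin, the glutamate receptor gene Grin3a, mt-Rnr1 and mt-Rnr2 were the genes furthest above 2L, with log2 ratios of 2L to 2R of -7.77, -6.48, -5.67, -5.88 and -5.43. In 4a the receptor genes Cnr1 and Ramp1 exceeded 4b by 4.33 and 4.16, followed by C1ql2, Retnla and Luzp2 at 3.56, 3.17 and 2.75. The genes furthest above 4a in 4b were small RNAs, Gm25099, Snora23, Gm25776, Snord15a and Snora78, at -3.17, -3.02, -2.88, -2.70 and -2.18. At least 2-fold differences were present in 16.6% of 10542 genes between 2L and 2R and in 3.94% of 10360 genes between 4a and 4b; each pair is 1 library against 1, without a test.

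Across the 11505 genes, same-number libraries had a mean gene-centred correlation of 0.177, against -0.128 for the other 26 pairs, a difference of 0.306 (one-sided exact permutation p = 0.0429; the smallest possible is 0.00476). The 4a and 4b correlation was 0.434 and that of 2L and 2R was -0.079. The difference was 0.00948 without 4b (exact permutation p = 0.571) and 0.0769 without 4a (p = 0.286, exact permutation). Without 1 or 3 the exact permutation p was 0.0571 or 0.0952.

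**Figure D3:**
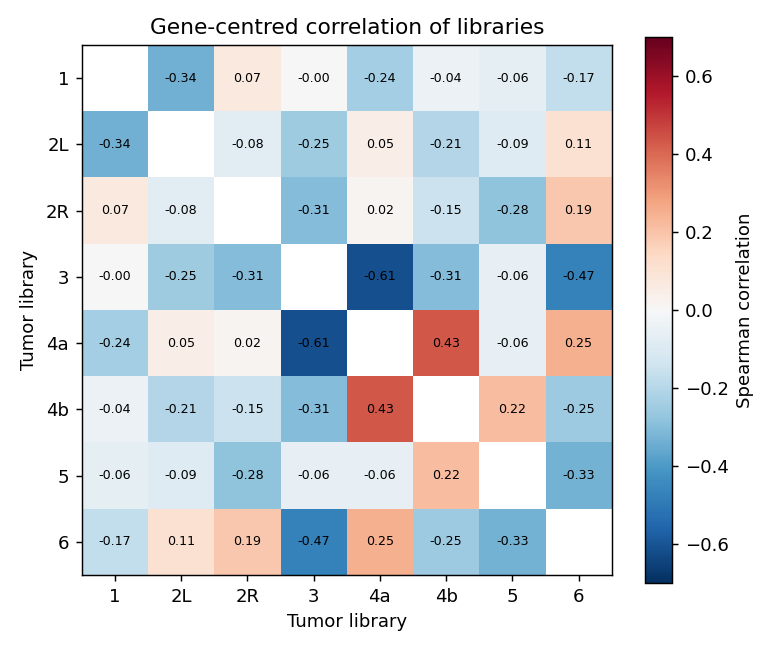
Spearman correlation of gene-centred log2 CPM between each pair of the 8 tumor libraries (both axes), with color and printed value giving the correlation; the diagonal is left blank. The pair 4a and 4b has 0.434, and 2L and 2R have -0.079.

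No gene was called among the 6 title numbers by edgeR's quasi-likelihood test (0 of 11505, smallest adjusted p = 0.0902), although 2813 genes had an unadjusted p under 0.05 where 575 would be expected by chance. The DESeq2 likelihood ratio test called 2383 genes. Without 2L or without 2R, when only 4a and 4b measured the spread within a number, edgeR called 4457 or 4548 genes and 11 lists were over-represented in each case. No fixed list was over-represented in the main test, where 0 genes were called, or among the 500 genes of smallest p (0 of 15 lists).

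Neuroendocrine genes had the smallest spread within pairs relative to other choices of pairs, but no list passed the correction. The neuroendocrine score was 5.80 in 1 and 2.43 in 6, against 4.59 and 4.41 in 2L and 2R and 3.72 and 4.03 in 4a and 4b (one-sided exact permutation p = 0.0429, adjusted p = 0.4 over 15 lists). The macrophage, locus, fibroblast and bone lists followed with exact permutation p of 0.0762, 0.0810, 0.129 and 0.133 (adjusted p = 0.4 for each).

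Scores of most lists varied more across the tumors than those of random lists of the same level, which members that are each variable can also give without moving together. The SD of the score exceeded the 95th percentile of random lists for 13 of 15 lists, with 2.16 for the mitochondrially encoded list (score 14.8 in library 3 and 8.39 to 11.9 elsewhere), 0.944 for the neuroendocrine, 0.893 for the matrix, 0.875 for the macrophage, 0.838 for the interferon and 0.822 for the endothelial list. The exceptions were the bone and cartilage list at the 94.8th percentile and the engineered loci at the 78.5th. As a description of levels, 12 of 15 lists had a median above the 50th percentile; neural crest, interferon and smooth muscle lists, at 43.1, 49.1 and 40.7, did not. Which lists lay above depended on the scaling by length: with CPM not scaled by length, neural crest and smooth muscle lay at 59.3 and 58.7, and neuroendocrine, interferon and proliferation lay below, at 35.2, 45.002 and 47.5.

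Proliferation scores ran opposite to macrophage and hypoxia scores over the 6 numbers, but 0 of 14 relations passed the correction. Proliferation with macrophage gave r = -0.913 (exact permutation p = 0.0125, adjusted p = 0.0875) and rho = -0.829 (exact permutation p = 0.0583, adjusted p = 0.272). Without 3 and 6, the 2 numbers furthest from the median proliferation score, r was -0.214, so the relation rests on those. No alternative run of the relations left out library 3 or 6. The adjusted exact permutation p was 0.0389 without 4a. It was above 0.05 under every other alternative run, from 0.0648 with the filter at a mean CPM of 5 to 0.369 with list medians. Proliferation with hypoxia gave r = -0.842 (exact permutation p = 0.00833, adjusted p = 0.0875) and rho = -0.771 (exact permutation p = 0.103, adjusted p = 0.288). Its r was -0.865 without the extremes and -0.392 when scores were list medians. With the filter at a mean CPM of 5 the adjusted exact permutation p was 0.0486. Every other alternative run left that p above 0.05, from 0.0583 without 4b to 0.783 with list medians. The melanocytic and neural crest scores, which share no tested member, gave r = 0.832 (exact permutation p = 0.0444, adjusted p = 0.207) and rho = 0.829 (exact permutation p = 0.0583, adjusted p = 0.272), with r = 0.0565 without the extremes. That relation depended on single libraries and on the members, with r = 0.273 without 2L, 0.951 without 2R (exact permutation, adjusted p = 0.0194), 0.953 without 4b (exact permutation, adjusted p = 0.0389), 0.401 without members shared between any of the lists, 0.123 with list medians and 0.201 with the filter at a mean CPM of 5. Atf1 did not track the CREB/ATF score (r = 0.0344, exact permutation p = 0.949; rho = 0.429, exact permutation p = 0.419) or Ewsr1 (r = 0.0495, exact permutation p = 0.928; rho = 0.143, exact permutation p = 0.803). The other 9 relations had exact permutation p of 0.239 to 0.865 for r and 0.0583 to 1 for rho. By rho the strongest of these were matrix with endothelial (rho = 0.829, exact permutation p = 0.0583, adjusted p = 0.272; r = 0.365, and 0.973 without the extremes) and melanocytic with proliferation (rho = -0.771, exact permutation p = 0.103, adjusted p = 0.288; r = -0.153).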

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

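All tests of explanations in this part were chosen after the values had been seen. The labels name 1 group, so the design itself offers no biological explanation to set against the technical ones. Of 171 values tested, 24 had a highest or lowest library far from the other 7 by Dixon's ratio of the gap to the range at its 95% critical value. Chance flags about 1 in 20 values, a rate that does not hold here for the genes chosen after their values were seen (Pvt1, Krt5, Adipoq and Flt1 among the 24). Library 3 held 14 of these, library 5 held 9 and library 6 held 1.

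In tumor 3 the proliferation genes Mki67 (396 CPM), Foxm1 (117 CPM) and Cdc20 (63.4 CPM), the melanocyte regulator Mitf (130 CPM), Krt5 (193 CPM), Pvt1 (7453 CPM) and mt-Co1 (218810 CPM) lay above the others. The receptor tyrosine kinase score (4.85), the matrix score (6.66), Pde4b (46.3 CPM) and Perp (145 CPM) lay below. The shares of Gm26917 with Gm42418 (27.6%), Gm23935 (12.3%) and mitochondrial protein-coding genes (18.7%) were also the highest in library 3. The TMM factor of library 3 (0.39) raises its CPM values about as much as its abundant RNAs lower them. CPM without it was computed only for Myc and Pvt1. Mitf had 245 of 4817902 counts in library 3 and 1011 of 19388408 in library 6. That share of all counts was slightly smaller in library 3. All genes outside the abundant noncoding and mitochondrial classes held 25.1% of the counts there, against 94.6% in library 6. The high place of Mitf thus appears only after scaling that offsets the abundant RNAs. In tumor 5 the Y-linked genes Ddx3y (120 CPM), Uty (56.9 CPM), Kdm5d (39.3 CPM) and Eif2s3y (18.5 CPM), the hemoglobin genes Hbb-bs (11794 CPM), Hbb-bt (2074 CPM) and Hba-a1 (408 CPM), and the fat cell genes Fabp4 (105 CPM) and Adipoq (4.63 CPM) lay above the others. Flt1 was lowest in tumor 6, at 11.9 CPM.

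Library 3 shared skeletal muscle transcripts with library 2L, and all 76 genes specific to 2L had counts in it, at a minimum of 0.327% and a median of 1.19% of their counts in 2L, with a maximum of 49.1% that such a share of reads cannot supply. In each of the other 6 libraries, over 67 to 114 genes chosen in the same way without that library, the minimum was 0. The common minimum in library 3, 0.327%, is consistent with reads of 2L having been counted in library 3. Muscle tissue in tumor 3 stays open beside this: 5 epithelial genes specific to 2L (Krt19, Itgb6, Slc34a2, Cst6 and Erbb3) stood at 0.827 times the median of 16 muscle genes (0.991% against 1.20%), but this ratio ran from 0.63 to 32.7 in the other 6 libraries, where epithelial genes reached 3.77% in 5 and 1.2% in 6. Ttn stood at 3.11% of its 2L count (9660 of 310590), 2.595 times the muscle median and above the other 15 muscle genes. Myh4 stood at 0.999% (852 of 85312). A single share of 2L reads would give both genes the same percent. These values argue against such reads as the whole source of Ttn in library 3.

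Myc and Pvt1, neighbors on chromosome 15 (Myc at 61985391 to 61990374), stood at 770 and 7453 CPM in library 3, against at most 70.0 and 34.8 CPM elsewhere. The normalization factor was excluded as the whole cause, since Myc without it was still 3.644 times the highest other library, and reads of another of these 8 libraries were excluded for Pvt1, whose count was 25.167 times the highest other count (for Myc, 1445 against 927); libraries outside the series were not tested. None of the 9 protein-coding neighbors exceeded its highest level elsewhere, and the highest, Asap1, reached 82.57% of it. The nearest of them lay 1132 kb from Myc (Fam84b) and 1551 kb from Pvt1 (Fam49b). A rise like that of Myc was thus absent in these neighbors. A smaller copy gain that reaches them cannot be excluded, because it could leave a gene within its range elsewhere. A gain confined to Myc and Pvt1 stays open as well, and RNA counts do not measure copy number. Outside this locus, the 98 genes at least 8 times higher in library 3 held 12 neighboring pairs within 500 kb. Over 1000 permutations of positions the median was 4 and the maximum 12 (permutation p = 0.002). Raised neighbors are thus not particular to the Myc and Pvt1 locus.

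Xist was counted 902 times in library 5 beside the Y-linked genes. The most Xist counts that the other 7 libraries could together have supplied, given the genes abundant in each that were scarcest in library 5, was 2933. Alone, 4b could supply 1391, 4a 975 and 2L no more than 12. Each limit treats all counts of those genes in library 5 as carried over, and the limits were summed. The sum is therefore a loose upper bound that cannot exclude counted reads of other libraries, which stay open as a source. Tissue of a female animal in the sample also stays open, because Xist stood at 9.47% of the median of the other 7 and no value here separates the explanations.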

How the results depend on the processing

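The settings without 2L and 3 together, and the filter at a mean CPM of 5 for list results, were chosen after seeing the data. Of the recomputed counts and tests, 15 became stronger and 5 weaker; none reversed. Mean CPM moved by less than 1 SD for every gene, but that SD is itself set by extreme libraries: leaving out 1 library lowered the mean over 1.5 times for 53 of 146 genes, 12 of them without library 3 (Pvt1 from 951 to 21.6, Krt5 from 24.5 to 0.322 and Gm26917 from 104138 to 31089). The edgeR count of genes differing among numbers was 0 with DESeq2 size factors, the filter at a mean CPM of 5, a prior that is not robust, thinned counts and library sizes without the most abundant genes. It was 2383 with the DESeq2 likelihood ratio test, 6260 without a filter (where the prior degrees of freedom were infinite for most genes, against a median of 3.39) and 2563 without 2L and 3; the cause was not tested. Leaving out each library gave 0 to 4548 genes and 0 to 11 over-represented lists, and a similarity difference of 0.00948 to 0.583. Without 2L and 3 the difference was 0.457 (exact permutation p = 0.0667), a design whose fewer libraries allow no p under 0.05. Relations between list scores passed the correction 2 times with the filter at a mean CPM of 5 and 0 to 1 times when 2L, 2R, 4a or 4b was left out (0 without 2L); removal of any other library leaves fewer than 6 numbers and was not run; the cause was not tested. The numbers of lists above the 50th percentile in level and above the 95th in score variation stayed within 1.5 times under every alternative run, but the lists differed: the neuroendocrine list moved from 62.3 to 35.2 with CPM not scaled by length. Depth limits library 3, where 3 counts are 1.60 CPM.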

Other observations

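The protocadherin beta cluster, 21 genes for neuronal adhesion proteins with a mean of at least 1 CPM, had a median of 13.6 CPM in tumor 1, 12.5 in 5, 11.1 in 4b, 6.29 in 4a, 6.07 in 2R, 5.33 in 2L and 2.68 in 6; in 3 it was 2.13, near the 1.60 CPM that 3 counts give there. This cluster belongs to no fixed list, was chosen after its values were seen, and was not tested. Of 13 protein-coding mitochondrial genes, which every cell uses, 5 are listed at 0 in all libraries, so the 0 says nothing of their expression. The mean of mt-Co1, 35823 CPM, was 9682 CPM without library 3.

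Whole chromosomes showed small shifts. Genes of chromosome 15 lay at a median log2 of -0.31 in 2R and 0.21 in 2L relative to the other libraries, and genes of chromosome 6 at 0.33 in 3, 0.23 in 5, 0.21 in 6 and -0.18 in 4b. The largest shift was -0.54 for the X chromosome in library 3, where chromosome 8 lay at 0.32. Of 160 chromosome and library combinations, 30 lay outside 1000 random gene sets of the same size; genes of a chromosome are not independent, and no cause was tested.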
